A study of Mus musculus with 4 samples.

How the data were processed

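Dorsal root ganglia of ICR mouse embryos were cultured for 48 h with 50 ng/ml nerve growth factor on fibronectin-coated inserts, per the labels' protocols. Material of whole ganglia was scraped from the upper face of the insert membrane. For the axon preparation that face was wiped clean and the membrane itself was extracted. The sample labels give embryonic day 13 and the series' design text day 13.5. That text gives 40 embryos per RNA sample, poly(A) selection and reads of 80 nt. The labels name 4 samples, 2 of whole ganglia and 2 of axons, and no source used here says whether duplicates came from separate cultures.

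The authors' deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped reads), in 2 tables, one for RefSeq and one for UCSC gene models. Each table had 2 value columns, 1 per compartment, and 0 columns of single samples. The tables' names call their transcripts merged. How the duplicates entered these columns is not given in the sources used here. Per the submitters' processing notes, the build was mm9 and the tools named included TopHat 1.2.0, Cufflinks 0.9.3 and HTSeq. FPKM of this kind are estimates that divide reads among overlapping transcripts. The RefSeq table held 22279 rows and 21848 symbols. Rows of the 217 symbols present on several rows were summed. A further 25 RefSeq rows carried gene names that had been turned into dates, and these were kept under those names. The UCSC table held 49407 rows, 69 of them with date-like names. Transcript starts in the tables count from 0, since in 6243 UCSC rows the length equalled end minus start and in 0 rows it equalled that difference plus 1. Coordinates are given 1-based on mm9.

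Read counts were not analysed here, and the depth of each sample is unknown. Low FPKM showed no whole-read steps that could be resolved. Among 9618 transcripts longer than 600 nt without an overlapping neighbour, the lowest FPKM above 0 times length was 434 in the ganglion column and 448 in the axon column. Weakly expressed transcripts therefore appear to be listed at 0 under a minimum. A value of 0 can also be a failed estimate, because 21 of 79 cytosolic ribosomal protein genes, which every cell uses, were listed at 0 in both columns. No fold is given against a value of 0.

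The test planned for values per sample was limma on log2(FPKM + 1). Columns of single samples were not among the values used here, so the branch fixed for pooled values was followed, with values and ratios and no p-value. The compartments were compared as log2(axon FPKM + 1) minus log2(ganglion FPKM + 1), which understates differences of weakly expressed genes. Genes with at least 1 FPKM in at least 1 compartment were kept. A gene is called higher or lower where the difference was at least 2-fold on that scale. Folds of single genes are ratios of FPKM. Before the data were examined, 25 gene lists were fixed, covering 782 measured genes, 19 of them in more than 1 list. For lists with at least 3 measured members, the median difference was placed among the medians of 10000 random lists of equal size drawn from 20 bins of mean level (seed 7). A list is described as above or below where its percentile was over 97.5 or under 2.5. This describes these columns and is not a test over replicates. With 24 lists, 1.2 would lie outside by chance if the members of a list varied independently. Genes of a list can vary together, which can put more lists outside and was not allowed for.

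The rule for naming genes asked for called genes. With none possible, its fallback was used: the 5 largest differences in each direction with at least 5 FPKM in the higher compartment, the 2 members of each list with the highest mean level, and Actb and Gap43. The fallback also asked for groups that do not overlap, which pooled columns cannot show. Other named genes, including the outermost members of each list, were chosen after their values were seen. Some genes that the rule selects are not reported here.

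The procedure was tested on simulated data with the 12615 genes of the axon against ganglion comparison. With an assumed noise of SD 0.3 on the log2 scale, 88% of the 100 genes shifted by log2 1.5 and 100% of the 100 shifted by log2 3 were recovered. The shifted genes were drawn from those with at least 5 FPKM in ganglia, so these rates do not cover weaker genes. The real noise is not known from pooled columns, so no rate of false calls is given. Lists of 30 random genes lay outside the limits in 6.5% of draws with no shift, 76.5% with a shift of 0.5 and 100% with a shift of 1.

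The alternatives were pseudocounts of 0.1 and 5, no level filter, a filter of 5 FPKM, quantile normalization, median centring, the UCSC table and rows as deposited. Detection was repeated at 0.1 and 5 FPKM. Added after seeing the data were a 4-fold limit, genes above 0 in both compartments, and random lists matched also on transcript length or GC content. Lengths came from the UCSC table. GC content came from GENCODE M21 transcripts by symbol, and no coordinate was taken from that annotation, which is on another build. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.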

Results

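RNA of cultured mouse dorsal root ganglia, which hold the cell bodies of sensory neurons with their glia, was compared with RNA of the peripheral axons that had grown from them. The comparison addressed which mRNAs the axonal compartment of sensory neurons contains. The labels name 2 samples per compartment, but the values used here were 1 FPKM column per compartment, not per sample. The differences below therefore have no replicate check, no error and no test, and sequencing depth is unknown. FPKM summed to 270622 in the ganglion column and 335890 in the axon column of the RefSeq table.

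Most genes detected in ganglia were also detected in the axon preparation. At 1 FPKM or more, 11979 genes were detected in ganglia and 12049 in the axon preparation. Both held 11413 genes, which is 95.3% of the ganglion genes. These counts describe the preparation and do not place each mRNA in sensory axons. Mesenchymal, macrophage, spinal cord and cell cycle lists lay above the random range in it, as given below. The Schwann and satellite glia list lay below that range, and the endothelial and erythroid lists inside. Only 79 genes passed 5 FPKM in axons while below 1 FPKM in ganglia, and 67 showed the opposite. Across genes, which are not independent replicates, log2(FPKM + 1) of the compartments correlated with a Pearson r of 0.81 and a Spearman rho of 0.81. Of the 12615 genes compared, 9235 (73.2%) lay within 2-fold. Another 1619 were at least 2-fold higher in axons, 181 of them listed at 0 in ganglia. At least 2-fold lower were 1761 genes, 113 of them listed at 0 in axons. With a pseudocount of 5 the counts were 819 higher and 874 lower. Among UCSC gene models 1557 genes were higher and 2661 lower, so the higher share was 36.9% against 47.9% in the RefSeq table, and the median of all genes was -0.19 against -0.02. Quantile normalization lowered the log2 differences of strongly expressed genes, among them Trp53inp2 (5.43 to 4.32), Kif1a (3.40 to 2.57), Rpl8 (2.24 to 1.39), Col1a1 (2.28 to 1.51) and Cox6a1 (1.90 to 1.08). It did so too for Cox8a (1.71 to 1.02), Aldoa (1.74 to 1.11), Fabp7 (0.79 to 0.06), Uchl1 (-1.21 to -1.98), Apoe (-1.57 to -2.57) and Sncg (-1.57 to -2.81).

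Among single genes, the 5 largest differences in log2(FPKM + 1) toward axons were those of Ccl5, Ifi27l2a, Plac8, Trp53inp2 and Trak2. Against a value of 0, the places of Ccl5, Ifi27l2a and Plac8 depend on the pseudocount. By ratio of FPKM other genes came before Trp53inp2, among them Ramp1 (58.1-fold, 0.24 FPKM in ganglia) and Hopx (48.7-fold, 0.69 FPKM in ganglia). Ccl5, a chemokine, was listed at 0 in ganglia and had 101 FPKM in axons (chromosome 11, 83339281 to 83344020). Ifi27l2a, an interferon-induced gene, had 56.7 FPKM in axons and Plac8 had 49.2, both listed at 0 in ganglia. Trp53inp2, which encodes a protein of autophagy, was 43.6-fold higher in axons, at 3528 against 81.0 FPKM (chromosome 2, 155207592 to 155215583). Trak2, an adaptor that links mitochondria to kinesin, was 38.5-fold higher, at 881 against 22.9 FPKM (chromosome 1, 58957294 to 59030326). Summed over UCSC models, the log2 differences were 5.29 for Trp53inp2 and 5.08 for Trak2. The highest level in axons in the RefSeq table was that of the imprinted non-coding RNA H19, at 10289 FPKM against 502 in ganglia (chromosome 7, 149761437 to 149764051). The microRNA gene Mir675 lies inside H19, and their reads cannot be told apart. Its imprinted neighbour Igf2 had 3896 against 371 FPKM, and Igfbp5, which encodes a binding protein of insulin-like growth factors, had 3224 against 270 FPKM.

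In the other direction, Cdh1, which encodes E-cadherin, was 70.1-fold lower in axons, at 1.10 against 77.1 FPKM (chromosome 8, 109127268 to 109194146). Mir715, Mir678 and Mir770 had 106, 22.5 and 21.6 FPKM in ganglia and were listed at 0 in axons. MicroRNA loci in a poly(A) library can hold reads of longer transcripts that overlap them. Mir770 lies inside the bounds of the RNA gene Meg3 on chromosome 12, which was itself 6.74-fold lower in axons.

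**Figure D1:**
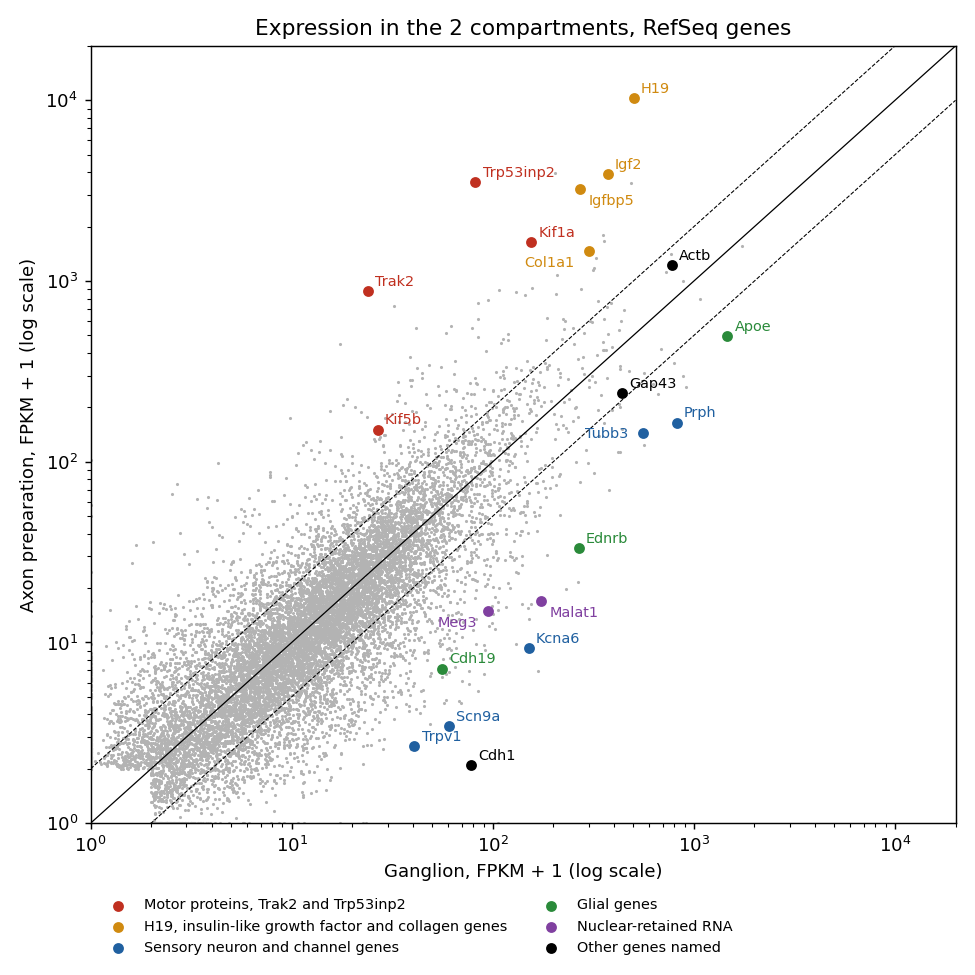
FPKM + 1 of each of the 12615 genes in ganglia (horizontal, log scale) and in the axon preparation (vertical, log scale), with 1 grey point per gene and named genes in colour. The solid line marks equal values and the dashed lines a 2-fold difference. Trp53inp2, Trak2, Kif1a and H19 lie far above the lines, and Cdh1, Trpv1 and Kcna6 far below.

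Genes that define sensory neurons were mostly lower in the axon preparation. Of 35 measured genes of sensory neuron identity, 26 were at least 2-fold lower and 3 higher, with a median log2 difference of -1.84, below all 10000 random lists (percentile 0). With a pseudocount of 5 the median was -1.21. The neuronal hydrolase gene Uchl1 had 269 against 624 FPKM. The transcription factor Isl1 had 12.4 against 47.3 FPKM. Ntrk2 was higher, at 33.7 against 13.1 FPKM. Of 50 ion channels 36 were lower and 2 higher, with a median of -1.83 (percentile 0). That median was -2.60 with a pseudocount of 0.1 and -1.05 with a pseudocount of 5, at percentile 0 in both. The ATP-gated channel P2rx3 had 14.4 against 149 FPKM and the potassium channel Kcna6 8.27 against 150.0 FPKM. The pain-related channels Scn9a and Trpv1, which are in both lists, had 2.43 and 1.67 FPKM in axons against 59.3 and 39.8 in ganglia. Of 34 synaptic vesicle genes 16 were lower and 2 higher, with a median of -0.91 (percentile 0). Sncg, which encodes a synuclein, had 298 against 883 FPKM, while the complexin gene Cplx2 was 4.89-fold higher, at 190 against 38.8 FPKM.

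The neuronal cytoskeleton list had 15 of 35 genes lower, 2 higher and 18 within 2-fold, with a median of -0.84 (percentile 0). The peripheral intermediate filament gene Prph had 164 against 821 FPKM, the neuronal tubulin Tubb3 143 against 555 FPKM and the neurofilament gene Nefl 113 against 421 FPKM. Tubb5 had 799 against 1066 FPKM, a log2 difference of -0.41 that became -1.80 after quantile normalization. The profilin gene Pfn1, whose product binds actin, was among the 2 higher members, at 598 against 228 FPKM. Actb, whose mRNA is known to be carried into axons, had 1226 against 773 FPKM, a log2 difference of 0.66 that became -0.36 after quantile normalization. Gap43, a growth cone protein gene, had 239 against 439 FPKM, a log2 difference of -0.87 that became -1.65 after the same normalization. Of 29 mRNAs reported in axons by earlier work, 6 were higher, 6 lower and 17 within 2-fold. Their median was 0.03 (percentile 11.45), and -0.11 after quantile normalization or in the UCSC table. Vim, an intermediate filament gene of that list, had 1556 against 1732 FPKM, a log2 difference of -0.15 that became -1.95 after quantile normalization.

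Motor proteins and their adaptors split, with 10 of 36 higher, 4 lower and a median of -0.03, inside the random range (percentile 5.76). The kinesin Kif1a, which carries synaptic vesicle precursors, was 10.6-fold higher, at 1636 against 154 FPKM (chromosome 1, 94912033 to 94998442). Kif1c had 115 against 11.5 FPKM and Kif5b, a conventional kinesin, 149 against 25.7 FPKM. In the opposite direction Kif21a had 18.4 against 81.2 FPKM and the dynein subunit gene Dync1i1 4.57 against 20.6 FPKM. Guidance and adhesion receptors had 16 of 42 lower, 7 higher, 19 within 2-fold and a median of -0.49 (percentile 0.11). Ncam1 had 23.1 against 132 FPKM and the contactin gene Cntn2 8.81 against 129 FPKM, whereas Robo1, a Slit receptor, had 20.7 against 6.24 FPKM. That list came inside the range when random lists were matched on transcript length too (percentile 2.93). Degeneration and apoptosis genes lay inside, with 2 of 35 higher, 4 lower and a median of -0.22 (percentile 10.96). App had 258 against 300.4 FPKM and the neurotrophin receptor gene Ngfr 27.7 against 127 FPKM. Sarm1, an executor of axon degeneration, had 4.81 against 17.4 FPKM, and the survival gene Bcl2l2 42.7 against 17.1 FPKM.

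The translation lists lay above the random range. Of 54 measured cytosolic ribosomal protein genes 48 were at least 2-fold higher, 8 of the 54 being listed at 0 in ganglia, and 0 were lower. The median was 1.86, above all 10000 random lists (percentile 100). Without the level filter the median of 79 genes was 1.38, and with a pseudocount of 5 it was 1.34 for the 54 (percentile 100 for both). Rpl8 was 4.72-fold higher, at 1675 against 355 FPKM. Rplp1 had 785 against 93.7 FPKM. Translation factors had 15 of 36 higher, 0 lower, 21 within 2-fold and a median of 0.81 (percentile 99.96). The elongation factor gene Eef1a1 had 775 against 333 FPKM, a log2 difference of 1.22 that became 0.48 after quantile normalization. Eef2 had 693 against 447 FPKM, a log2 difference of 0.63 that became -0.28. The poly(A)-binding protein gene Pabpc1 had 262 against 52.2 FPKM. The cell cycle and mesenchymal lists had medians of 0.88 and 1.79 in the same columns.

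The lists of energy metabolism differed in how many genes passed 2-fold. Of 69 nuclear genes of the respiratory chain 23 were higher, 0 lower and 46 within 2-fold, with a median of 0.76 (percentile 100). The cytochrome oxidase subunit genes Cox6a1 and Cox8a had 1182 and 903 FPKM in axons against 316 and 275 in ganglia. Mitochondrial ribosomal protein genes had 9 of 75 higher, 0 lower, 66 within 2-fold and a median of 0.37 (percentile 99.98), with Mrpl52 at 156 against 45.1 FPKM and Mrpl54 at 82.0 against 35.3 FPKM. Both lists came inside the random range once transcript length was matched too, with percentiles of 77.58 and 84.23. Of 17 glycolysis genes 9 were higher and 0 lower, with a median of 1.03 (percentile 99.95). The aldolase gene Aldoa had 622 against 186 FPKM, Pkm2, a pyruvate kinase gene, 290.2 against 80.6 FPKM and hexokinase gene Hk2 20.9 against 2.79 FPKM.

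Transcripts of the mitochondrial genome were present in the UCSC table alone. Of its 8 mitochondrial rows 6 were above 0, and all 6 were higher in axons, by 3.40-fold to 62.8-fold with a median of 6.06-fold. The 62.8-fold difference was that of AK140265 (positions 70 to 852). The next largest was 11.9-fold, for AK018753 (positions 1149 to 3703). The transcript mt-Nd4, a subunit of the first respiratory complex, had 8035 against 1388 FPKM (positions 9876 to 11542). X57780, at positions 12406 to 15288, had 12434 against 2458 FPKM. Cox2 and Atpase6 were listed at 0 in both columns. Taken as FPKM times length, mitochondrial transcripts held 14.5% of mapped reads in axons and 1.97% in ganglia. By the same measure the 10 non-mitochondrial genes with the largest share in the UCSC table held 9.86% in axons and 2.44% in ganglia.

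Marker genes of other cell types differed in both directions. Schwann cell and satellite glia genes were lower, with 16 of 23 lower, 1 higher and a median of -1.57 (percentile 0). The lipoprotein gene Apoe had 494 against 1464 FPKM and the endothelin receptor gene Ednrb 32.2 against 266 FPKM. Fabp7, a lipid-binding protein gene of glial progenitors, had 618 against 356 FPKM, and Zeb2, the higher member, 169 against 64.1 FPKM. Fibroblast and mesenchymal genes were higher, with 22 of 27 higher, 1 lower and a median of 1.79 (percentile 100). The collagen genes Col1a1 and Col3a1 had 1462 and 1340 FPKM in axons against 300.1 and 324 in ganglia, and smooth muscle actin gene Acta2 35.0 against 1.05 FPKM. Sparc had 1003 against 881 FPKM, a log2 difference of 0.19 that became -1.25 after quantile normalization. Ogn was the lower member, with 51.9 FPKM in ganglia and a log2 difference of -2.14.

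Macrophage and immune genes had 11 of 16 higher, 0 lower and a median that was 2.29-fold on the FPKM + 1 scale (percentile 100), with Lyz2 at 129 against 86.8 FPKM and Tyrobp at 74.3 against 27.1 FPKM. Cell cycle genes had 14 of 36 higher, 0 lower and a median of 0.88 (percentile 100), and all 36 had the larger value in axons. The replication gene Mcm6 had 63.8 against 23.2 FPKM and the topoisomerase gene Top2a 51.7 against 19.2 FPKM. Of the 23 genes in the list fixed for spinal cord progenitors and motor neurons, all 13 measured were higher, with a median of 2.06 (percentile 100). The 13 were Olig1, Olig2, Nkx2-2, Nkx6-1, Pax6, Slc1a3, Hes5, Lbx1, Gad1, Slc32a1, Pax2, Lhx1 and Lhx5. Just 1 of them reached 1 FPKM in ganglia and 7 were listed at 0 there, so the others were kept by the level filter through their axon value alone. Without that filter the 23 genes had a median of 1.36, and with a pseudocount of 5 the median of the 13 was 0.80 (percentile 100 for both). It was 3.87 with a pseudocount of 0.1, and 3.06 over the 4 genes left by a filter of 5 FPKM. The glutamate transporter gene Slc1a3 had 112 against 12.6 FPKM and the progenitor factor Olig1 15.7 against 0.98 FPKM. The growth protocol in the labels covers spinal cord explants besides ganglia. Endothelial genes had 3 of 10 higher, 0 lower and a median of 0.44 (percentile 91.35), with Cdh5 at 43.4 against 23.7 FPKM and Emcn at 26.3 against 5.87 FPKM. That list lay above the range with a filter of 5 FPKM (median 1.06, percentile 99.28) and in the UCSC table (99.12). Erythroid genes did not stand apart, with 0 of 5 past 2-fold and a median of -0.09 (percentile 34.61). The embryonic globin gene Hbb-y had 129 against 137 FPKM and Hba-x 37.6 against 33.0 FPKM.

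RNAs known to stay in the nucleus were lower in axons, with 7 of 10 lower, 0 higher and a median of -2.12 (percentile 0), or -1.53 without the level filter. Malat1 was 10.8-fold lower, at 16.0 against 172 FPKM (chromosome 19, 5795690 to 5802671), and the imprinted RNA Meg3 6.74-fold lower, at 13.9 against 93.9 FPKM. Tug1 had 41.5 against 58.8 FPKM. Hox transcription factors had 11 of 31 higher, 3 lower and a median of 0.51 (percentile 99.97). Without the level filter the Hox median was 0.17 (percentile 99.88). Hoxb8 had 74.3 against 12.0 FPKM and Hoxb9 72.0 against 10.9 FPKM. The 3 lower members were Hoxd1, Hoxd3 and Hoxd4. Splicing and nuclear RNA processing genes lay inside the range, with 6 of 52 higher, 0 lower and a median of 0.28 (percentile 91.14), Hnrnpu having 197 against 125 FPKM and Hnrnpa2b1 164 against 111 FPKM. Proteasome genes showed 0 of 31 past 2-fold and a median of 0.38 (percentile 85.52), with Psmb4 at 199 against 116 FPKM and Psma7 at 152 against 100.3 FPKM. In all, 10 of the 24 lists compared lay above the random range, 7 below and 7 inside. The list of mitochondrially encoded genes had no row in the RefSeq table.

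**Figure D2:**
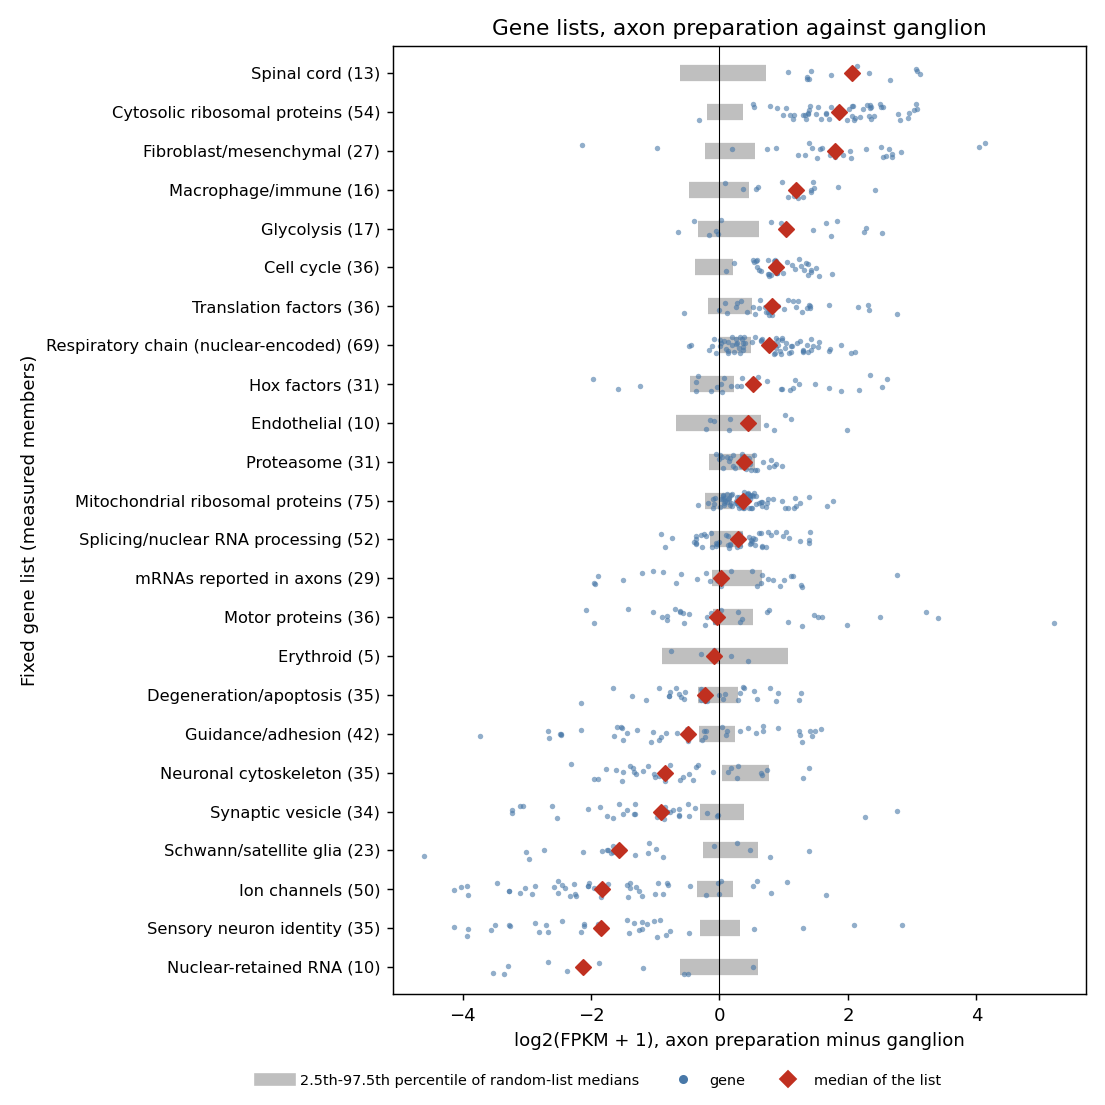
Difference in log2(FPKM + 1), axon preparation minus ganglion, for the 24 fixed gene lists, with 1 blue point per measured gene and the list's median as a red diamond. Grey bars span the random range of medians of 10000 lists matched on level, inside which a list was not set apart. Spinal cord and cytosolic ribosomal protein medians (2.06 and 1.86) lie highest, and sensory neuron identity and nuclear-retained RNA medians (-1.84 and -2.12) lowest.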

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

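A 4-fold limit, genes above 0 in both compartments and random lists matched on length or GC content were chosen after seeing the data. With a pseudocount of 5, 1693 genes passed 2-fold (819 higher, 874 lower), since a larger pseudocount shrinks differences of weakly expressed genes. The 4-fold limit left 727 genes (355 higher, 372 lower). Among UCSC gene models 2661 genes were lower, and the cause was not tested. Under the other settings run, the number of differing genes stayed between 2717 and 4187, within 1.5 times 3380. Detection counts stayed within that factor from 0.1 FPKM (13457 in ganglia, 13430 in axons) to 5 FPKM (9008 and 8629). Of 285 list medians under alternatives 45 moved by more than the SD of the random medians, and of 499 values of 57 named genes 36 moved by over 1.5-fold. Among lists outside the range and genes past 2-fold that the naming rule selects, 0 changed sign. Under the scalings and the UCSC table, the list members past 2-fold that changed sign were Eno1 (1.46 to -1.58), Hnrnpa1 (1.09 to -1.64), Rps12 (1.38 to -0.35) and Scn8a (-1.25 to 0.72), each with UCSC gene models. All 17 lists outside the range kept their side under each planned setting run, except that nuclear-retained RNAs were not computed in the UCSC table. Matching on length kept 13, with that list again not computed and the respiratory chain, mitochondrial ribosomal and guidance lists inside. With random genes from outside the fixed lists it kept 14, guidance receptors were below (2.46) and splicing genes above (97.95). Matching on GC content kept 17. Unknown depth limits what a value near 1 FPKM or listed at 0 can show. No paired analysis was possible because each compartment had a single column. For that reason limma without its trend, an adjusted p of 0.1, the set tests, leaving out each sample and the agreement of duplicates were not run. Alternatives for counts were not run because the values were FPKM.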

Other observations

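Of the tests in this part, the length test of the mesenchymal, macrophage, spinal cord and cell cycle lists and the interferon test were set out before their results were seen. The other tests were chosen after. The length test of the translation and mitochondrial lists was split after a joint test had been run, and the GC test was narrowed to the translation lists. The hypoxia and interferon lists were drawn up after the genes highest in axons had been seen.

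The hypoxia response list was examined in the axon preparation. Of 33 measured members 22 were at least 2-fold higher and 0 lower, with a median of 1.67. Ndufa4l2, a mitochondrial protein gene induced by hypoxia, had 74.6 against 1.70 FPKM, Ppp1r3c 65.0 against 1.53 FPKM and the oxygen sensor Egln3 31.0 against 2.37 FPKM. Vegfa differed little, at 33.7 against 30.7 FPKM, and Ndrg1 had 81.9 against 142 FPKM, within 2-fold. Without members among the 60 genes highest in axons, 17 of 28 were higher, and the median of 1.53 lay above all random lists (percentile 100). Leaving out glycolysis genes too left 19 members with a median of 1.44 (percentile 100). These values do not separate a response to low oxygen from a different mix of cells.

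The interferon list was similar, with 22 of 31 members at least 2-fold higher, 0 lower and a median of 1.36. Irf7, a regulator of interferon genes, had 61.1 against 2.40 FPKM, Ifitm3 563 against 61.3 FPKM and Isg15 57.3 against 8.85 FPKM. Stat2 had 11.8 against 21.9 FPKM, within 2-fold. Without members among the 60 highest genes, 18 of 27 were higher and the median was 1.32 (percentile 100). These values do not separate an interferon response from immune cells, whose own list lay at percentile 100.

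The mesenchymal, macrophage, spinal cord and cell cycle medians lay above the random range in a preparation named for axons. With length matched, the lowest percentile of the 4 lists was 100. This argues against transcript length as the whole cause for the macrophage and spinal cord lists. Their median lengths were 1497 and 2289 nt, against 2555 nt for all genes. The mesenchymal and cell cycle lists were longer, at 3184 and 2900 nt. Differences fell with length across genes (Spearman rho -0.23), so matching had little to decide for these 2 lists. A loss of neuronal transcripts alone, raising all other cell types alike, is argued against by the Schwann and satellite glia median of -1.57. That median was already known when the test was chosen. It cannot decide on a loss of neuronal and glial transcripts together, which was not tested. Non-neuronal cells or their RNA cannot be told apart from a difference between axons and cell bodies. The cell cycle median, at percentile 100, is part of the pattern and decides nothing. Of the 27 mesenchymal genes 22 were higher and 1 lower, with Col1a1 at 1462 against 300.1 FPKM.

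The medians of the cytosolic ribosomal protein, translation factor, respiratory chain and mitochondrial ribosomal lists lay above the random range, with 48 of 54, 15 of 36, 23 of 69 and 9 of 75 genes at least 2-fold higher. For the cytosolic ribosomal and translation lists, length and GC content as the whole cause are argued against by lowest percentiles of 99.97 and 99.99 when these were matched. Length may account for the respiratory chain and mitochondrial ribosomal lists, whose higher percentile with length matched among all genes was 84.23. With length matched and random genes from outside the fixed lists, their percentiles were 86.96 and 89.12, also inside the range. Their median transcript lengths were 679 and 1029 nt against 2555 nt for all genes, and across genes length and difference had a Spearman rho of -0.23. Local enrichment in axons and RNA from dividing cells both stay open for the translation lists.

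Trp53inp2, Trak2 and Kif1a were far higher in axons, while the sensory neuron identity list had 26 of 35 genes lower. Division of reads among each gene's own models as the cause is argued against. Summed over UCSC models, the lowest log2 difference of these genes was 3.35. Reads shared with other overlapping genes were not examined. Single Kif1a models differed in direction, with uc007cdg.1 at log2 -3.52 and uc007cde.1, uc007cdf.1 and uc007cdh.1 at 4.29, 3.22 and 4.14. RNA of the cells behind the mesenchymal markers cannot be told apart from axonal enrichment, since no value here gives the level of these 3 genes in such cells. Although 0 mesenchymal members were raised as much as Trak2, Acta2 and Tagln had log2 differences of 4.13 and 4.05, above the 3.40 of Kif1a. Tbc1d9b, at 727 against 31.2 FPKM, and Nes, at 449 against 16.4 FPKM, had differences of similar size.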
